A study of Homo sapiens with 40 samples.

How the data were processed

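Total RNA from 40 human samples of non-ETP T-cell acute lymphoblastic leukaemia (T-ALL; ETP stands for early T-cell precursor) was measured on Affymetrix HT HG-U133 Plus PM arrays, 1 array per sample. The samples were leukaemic blasts taken at diagnosis, kept frozen as mononuclear cells of marrow or blood. The labels place all 40 samples in 1 group and name no controls, so each sample is called by its replicate number, which carries no order. Each array holds 54715 probe sets, which are groups of short probes for a transcript. The deposited values are log2 expression levels, made by the authors with the RMA method, per the submitters' processing notes. RMA corrects background, quantile normalizes the arrays and summarises the probes of a probe set. Its version, the chip definition and any other arrays normalized together are not given in the sources used here. The values ran on a log2 scale with array medians between 3.13 and 3.24, and they were used without further scaling. Array values have no read depth; the number of arrays and, for dim genes, the signal over background limit the precision.

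Gene names came from the platform's probe set table, in which 40920 probe sets carried a single gene symbol, 864 carried several and 12931 carried none. Of the first kind, 40864 matched a gene identifier of the RefSeq gene table (assembly GRCh38.p14), which was used for names and chromosomes only. No coordinates are given, since the sources name no genome build. XIST and Y-linked genes (59 probe sets) were left out of all values per gene. Array medians, correlations between arrays, quantile normalization and the search for probe sets that follow PRMT1 used all probe sets. A gene's value was that of its single-symbol probe set with the highest mean, which gave 19738 genes. Probe sets differ in affinity, so levels of different genes are not comparable with each other. Genes of the fixed lists without such a probe set were not analysed here.

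The background of an array was the 95th percentile of the 74 probe sets of 50 genes of unrelated tissues, such as liver, eye and skin. It averaged 3.65 ± 0.22 log2 (SD, n = 40 arrays). A gene was tested when above background on at least 4 arrays (11955 genes) and called present when above it on at least 20 arrays (9985 genes). The gene lists, the pairs to correlate, the tests, the named-gene rule and most of the alternatives were fixed before the data were examined. The lists held 182 epigenetic genes in 9 classes, 17 of them known to be mutated in T-ALL. The other lists held T-ALL oncogenic transcription factors, targets of the TAL1 complex and of NOTCH1, tumour suppressors, and genes of proliferation, immature or stem-like cells, cortical thymocytes, mature T cells, all T cells, the interferon response and the immediate early response. Markers of B cells, monocytes, granulocyte precursors, erythroid cells, NK and cytotoxic cells and platelets stood for other cell types, and no gene stood in more than 1 of these lists.

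The spread of a list was the median SD of its genes, compared with 10000 random lists matched on size and mean expression in 20 bins (permutation p, two-sided). Separate sets of samples were sought by a likelihood ratio of a mixture of 2 normal components of equal variance against 1 component. Its p came from 1000 simulations, whose smallest value is 0.001, and a call also needed means over 4 component SDs apart. A score was the mean of the z-scored tested genes of a list. Scores and fixed gene pairs were correlated with Pearson's r and Spearman's rho, each with a two-sided permutation p from 100000 resamples, whose smallest value is 1e-05. Below 10 samples every permutation was enumerated for an exact p. For correlations and the sets of a score, a split needed an unadjusted p under 0.05 and means over 4 component SDs apart. Where a measure formed such separate sets, correlations were computed within sets of at least 6 samples. Each tested gene was regressed on a score standardised to an SD of 1 with limma (eBayes with trend), leaving out the genes of that score. A slope is therefore a log2 change per SD of the score, and "rose" or "fell" means a positive or negative slope past the threshold. Epigenetic lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Multiple tests were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 on the adjusted p. The p-values of mixtures, correlations and regressions measure only the spread between these samples. Those against random lists measure the spread between genes, with the samples held fixed.

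Named genes were the 17 mutated epigenetic genes, the oncogenic transcription factors with 2 components, the 15 genes with the largest SD, the 8 epigenetic genes with the largest and the 5 with the smallest SD, and members of the fixed pairs. In each regression the rule named up to 8 epigenetic genes by smallest adjusted p and the 5 genes with the largest slope in each direction. For other lists it named 2 to 4 members with the largest mean or SD; further members named in the text were chosen after their values were seen. RNA quality was read from the control probe sets as the 3-prime to 5-prime log2 ratio of GAPDH and of ACTB. The labels describe 3 arrays as additional and 37 as taken from earlier records, and this technical split was tested as a batch check. The alternatives covered other background levels and filters, other probe sets per gene, quantile normalization, array weights, control ratios and cell type scores as covariates, and samples left out. Principal components used the 2000 most variable genes.

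On simulated data of 11955 genes for the proliferation regression, 77% of genes with a slope of 0.5 and 39% of genes with a slope of 0.25 were recovered, and 9 of 11725 unchanged genes were called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and mclust 6.1.1 were used.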

Results

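Gene expression was profiled in 40 samples of non-ETP T-ALL, a cancer of T-cell precursors, with 1 array per sample and no control samples. All samples belonged to 1 group, so the comparisons ask which genes differed between leukaemias and which went together. The series is part of a study of altered epigenetic genes in cancers, and genes that write, read, erase or remodel chromatin marks therefore come first. Arrays resembled each other, with a pairwise r from 0.897 to 0.984 across probe sets, which are not independent replicates. Between 8897 and 11277 genes were above background per array. The GAPDH control ratio lay above 1 log2 on 3 arrays and at or below 0.51 on the other 37.

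Nearly every epigenetic gene was detected in these leukaemias. Of the 173 measured, 166 were present, against 50.6% of all 19738 genes, and 152 were above background on all 40 arrays. Presence was complete for the Polycomb repressive complex 2 (PRC2, which methylates histone H3 at lysine 27), the histone demethylases, the acetyltransferases, the DNA methylation genes and the chromatin readers. The measured genes below the limit were SETD1A, PCGF2, HDAC10, HDAC11, SIRT6, SMARCA1 and SMARCD3, named after their values were seen. No test was run on presence.

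All 17 epigenetic genes known to be mutated in T-ALL were present, 15 of them on all 40 arrays by the same measure. EZH2, the methyltransferase of PRC2, averaged 7.83 ± 1.11 log2 (SD, n = 40), EED 7.41 ± 0.54 and SUZ12 9.04 ± 0.37, both core partners of EZH2. PHF6, a plant homeodomain protein of the nucleolus, averaged 8.19 ± 0.86 and USP7, a deubiquitinase, 9.24 ± 0.66. The DNA methyltransferase DNMT3A averaged 8.73 ± 0.47 and TET2, which oxidises methylated cytosine, 5.33 ± 0.98. Mean levels of the H3K4 methyltransferases KMT2A, KMT2C and KMT2D were 8.52 ± 0.37, 8.25 ± 0.32 and 8.21 ± 0.34. The H3K36 methyltransferase SETD2 averaged 7.96 ± 0.31 and the H3K27 demethylase KDM6A 5.96 ± 0.78. The acetyltransferases CREBBP and EP300 averaged 7.33 ± 0.48 and 7.53 ± 0.42. ASXL1, a cofactor of a histone H2A deubiquitinase, averaged 7.53 ± 0.42, CTCF, an insulator protein, 8.54 ± 0.34, and SMARCA4, an ATPase of SWI/SNF remodellers, 9.23 ± 0.57.

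Epigenetic genes varied between leukaemias about as much as other genes of like signal, while genes of thymocyte stage, of T-ALL oncogenes and of other blood cells varied far more. The median SD of the 171 tested epigenetic genes was 0.42 log2, which was 0.977 times the median of matched random lists (permutation p = 0.541, adjusted p = 0.561, n = 40). The 9 epigenetic classes had ratios from 0.827 for acetyltransferases to 1.24 for PRC2, the mutated genes had a ratio of 1.14, and none passed the test (adjusted p from 0.195 to 0.768 for these lists). The widest spread was in erythroid genes, at 4.55 times random lists, with the haemoglobin genes HBD at 10.10 ± 2.13 log2 and HBM at 8.44 ± 2.28. Cortical thymocyte genes followed at 3.76 times, led by the lipid antigen-presenting molecules CD1E (9.59 ± 3.41) and CD1B (8.22 ± 2.96). The monocyte list had a ratio of 3.66, with LYZ (lysozyme) at 8.84 ± 1.92 and S100A8 at 9.81 ± 1.85, and the oncogenic transcription factors had a ratio of 3.42. Targets of NOTCH1, a receptor often activated in T-ALL, had a ratio of 2.75 and included CR2 (8.28 ± 2.55) and HES1 (7.47 ± 1.78). The immature or stem-like list, with PROM1 (4.53 ± 2.49) and SPINK2 (6.77 ± 2.32), had a ratio of 2.68. Granulocyte precursor genes, with MPO (myeloperoxidase) at 5.02 ± 1.71, had a ratio of 2.67. The mature T cell list, with the activation marker CD69 at 7.14 ± 2.04, had 2.66, and NK and cytotoxic genes, with KLRB1 at 5.73 ± 1.61, had 2.63. Interferon response genes had a ratio of 2.20, with IFI44L at 4.67 ± 1.84 and MX2 at 7.51 ± 1.41. Lower ratios were found for TAL1 complex targets (2.13), immediate early genes (1.90), B cell markers (1.87), tumour suppressors (1.72), proliferation genes (1.67) and pan T cell genes (1.59). Each of these lists passed the test (adjusted p from 0.000933 to 0.0402), but the 2 tested platelet genes PF4 and PPBP, at a ratio of 2.01, did not (adjusted p = 0.195). The p-values against random lists take the genes of a list as independent, which genes that vary together are not. With the median absolute deviation in place of the SD, the calls ended for oncogenes (ratio 1.22), immature genes (1.46), pan T cell genes (1.56), tumour suppressors (1.21) and B cell markers (1.59). The calls also ended for TAL1 complex targets (1.77) and pan T cell genes (1.24) with the median of probe sets, and for pan T cell (1.34) and B cell genes (1.69) with the probe set of largest SD. With the monocyte, erythroid, B cell and NK scores regressed out, the calls ended for pan T cell, B cell, monocyte, erythroid and NK genes (ratios from 1.05 to 1.39), the last 4 being the scored lists themselves. By the median absolute deviation, histone methyltransferases varied less than random lists, at a ratio of 0.750 (adjusted p = 0.00967), and without the 3 arrays of high GAPDH ratio so did acetyltransferases, at 0.715 (adjusted p = 0.0161).

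**Figure D1:**
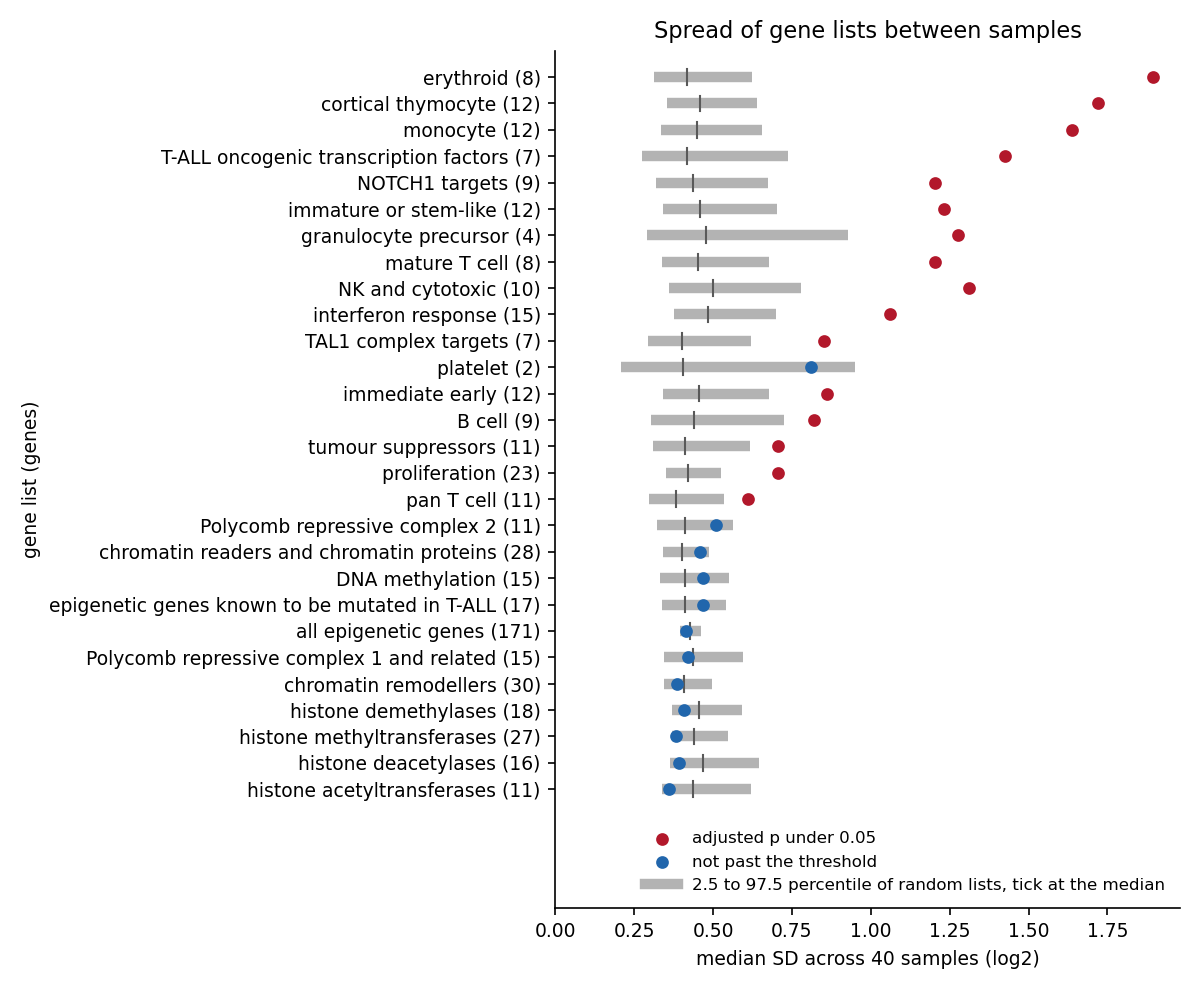
Median SD across 40 samples (log2, x axis) of the tested genes of each list, with the number of genes in parentheses. Grey bars span the central 95% of random lists matched on size and mean expression. Red points, from the pan T cell to the erythroid list except the platelet list, have an adjusted p under 0.05, and the epigenetic lists lie within their bars.

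Among single genes, ALDH1A2, an enzyme that makes retinoic acid, varied most (8.49 ± 3.63 log2, SD, n = 40), followed by CD1E, CSMD1, TMSB15A and CD1B. IGLL1, a surrogate light chain of B-cell precursors, XG, ZNF423, the homeobox gene IRX3 and the sodium channel gene SCN7A came next. The list of the 15 largest SDs ended with DUXAP10, KANK4, GTSF1, the sodium channel gene SCN2A and the complement receptor gene CR2, whose SD was 2.55. Of the tested genes, 1214 (10.2%) had an SD over 1 log2 and 84 an SD over 2. Only 3 epigenetic genes were among the former: PRMT1 (SD 1.43), the main enzyme for asymmetric arginine methylation, HDAC4 (1.21), a deacetylase, and EZH2 (1.11). A single sample lay apart in EZH2, and the SD within the 2 sets was 0.73. The DNA methyltransferase DNMT3B, the demethylase KDM7A, the Polycomb protein CBX2, TET2 and the remodeller SMARCA2 followed, in that order, with an SD of 0.98 for SMARCA2. The smallest SDs among present epigenetic genes were those of TRIM33 (0.19), BRD7 (0.19), MBD4 (0.20), HDAC2 (0.22) and KAT6A (0.22). Expression of 21 of 166 epigenetic genes formed 2 separate sets of samples, but in 13 of them the smaller set held under 4 samples. The other 8, named after their values were seen, were PRMT1, PHF6, ASXL2, HAT1, SMARCD2, ARID1A, CHD4 and HELLS. The lower set held 15 samples for PRMT1, 6 for PHF6 and 6 for HELLS, a remodeller needed for DNA methylation.

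Of the T-ALL oncogenic transcription factor genes, TLX1, NKX2-1 and MEIS1 were high in a few samples and near background in the rest, while LMO2 and LYL1 were above background on all 40 arrays. Expression formed 2 sets for 8 of the 15 measured genes (simulated p = 0.001, the smallest that 1000 simulations can give, adjusted p = 0.00187 for each). TAL1, a basic helix-loop-helix factor of blood stem cells, was in the higher set in 17 samples, with levels from 2.34 to 7.95 log2, and above background on 24 arrays. The homeobox gene TLX1 was high in 3 samples and NKX2-1, normally a lung and thyroid factor, in 4, with sets 16.2 and 16.3 component SDs apart. MEIS1, a homeobox partner of HOX proteins, was high in 7 samples, and MEF2C, a MADS-box factor, in 5. TLX3 had 5 samples in its higher set, but only 3 arrays exceeded background. LMO1 and BHLHE22 were each higher in 1 sample. The other 7 genes, LMO2 and LYL1 among them, had a single set by this rule, although LMO2, the bridge of the TAL1 complex, ranged from 5.04 to 11.41 log2 (SD 1.42, n = 40). BHLHE22 was not called without the 3 arrays of high GAPDH ratio. The sizes of some sets depended on the assumption of equal variance. With unequal variances the higher set held 24 samples for TAL1, 8 for TLX3, 7 for MEF2C and 2 for LMO1. Their means lay 2.29, 1.57, 1.68 and 1.37 of the larger component SD apart, although 2 components were still favoured over 1. MEIS1 (7 samples) lay 3.73 apart, and TLX1 (5.01) and NKX2-1 (5.98) over 4.

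**Figure D2:**
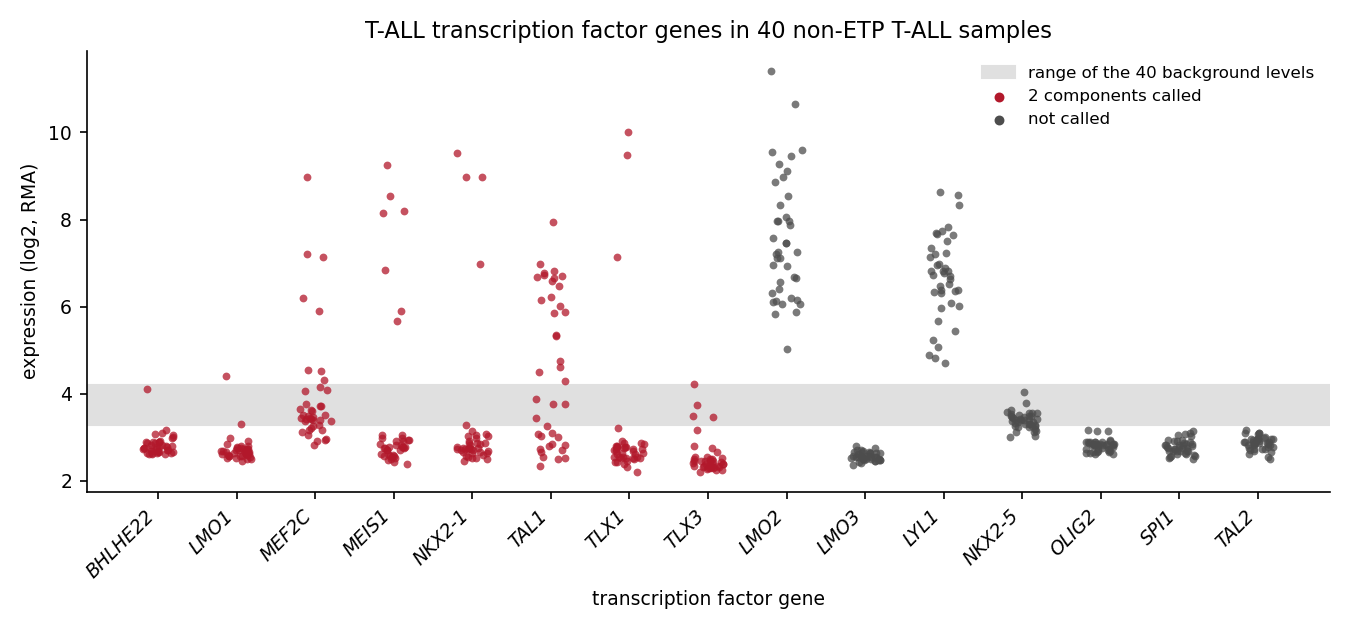
Expression (log2, y axis) of 15 T-ALL transcription factor genes in 40 samples, each point a sample. Red genes formed 2 sets of samples, such as NKX2-1 with 4 and MEIS1 with 7 samples in the higher set, and the grey band is the range of the background levels of the 40 arrays.

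Leukaemias with higher expression of cell cycle genes had higher expression of ASF1B, H2AX, EZH2, EED, DNMT1 and UHRF1, and lower expression of JMJD1C and KDM5B. ASF1B, a chaperone that hands histones to new DNA, rose 1.60-fold per SD of the proliferation score (slope 0.68 ± 0.07 SE, adjusted p = 7.09e-10, n = 40). H2AX, the histone variant of the DNA damage response, had a slope of 0.58 ± 0.07 and SUV39H2, an H3K9 methyltransferase, 0.58 ± 0.08 (adjusted p = 4.09e-08 and 3.25e-07). In EZH2 and DNMT1 the same 1 sample lay far below the mean of the others (2.69 against 7.96 and 7.34 against 9.38 log2). For H2AX 1 sample did so (5.84 against 9.03), and for UHRF1 2 samples (7.93 against 10.26). The slopes include these samples. JMJD1C and KDM5B, members of the demethylase list, fell by 0.24 and 0.31 log2 per SD (adjusted p = 0.000312 and 0.0117). Of 171 epigenetic genes 24 rose and 5 fell, or 29 and 8 adjusted over the list alone, against 1171 that rose and 326 that fell among all 11932 tested genes (12.5%).

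Chromatin readers and chromatin proteins rose as a class, with 8 of 28 members up and none down (10 and 0 adjusted over the list alone). The 8 were ING1, ING2, CTCF, the histone variants H2AZ1 and H2AX, the assembly genes CHAF1A and CHAF1B, and the chaperone gene ASF1B. For short, this mixed list is called readers or reader genes below. The camera test gave adjusted p = 0.000213, but adjusted p = 0.204 with an estimated correlation. Its members CHAF1B, a subunit of the chromatin assembly factor, and H2AZ1, a histone variant at promoters, had slopes of 0.42 ± 0.06 and 0.21 ± 0.03 (adjusted p = 1.56e-06 and 4.20e-06). In PRC2, EZH2, EED, SUZ12 and RBBP7 rose and none of 11 members fell, or 7 and 3 adjusted over the list alone. EED had a slope of 0.40 ± 0.06 (adjusted p = 3.11e-06) and EZH2 0.76 ± 0.13 (adjusted p = 2.80e-05). The set test for PRC2 did not pass (adjusted p = 0.0571, and adjusted p = 0.310 with an estimated correlation), but it passed with quantile normalization (0.0462), without the 3 additional arrays (0.0484), with 4 cell type scores as covariates (0.0341) and against random lists (p = 0.003), the last chosen after the data were seen. The methyltransferases SUV39H1 (0.31 ± 0.05) and NSD2 (0.40 ± 0.06) rose with SUV39H2, while KMT5B, an H4K20 methyltransferase, fell by 0.16, which left 3 up and 1 down among 27 (3 and 1 adjusted over the list alone). In DNA methylation genes, DNMT1, UHRF1, MBD2 and IDH2 rose and none of 15 fell (4 and 1 adjusted over the list alone). Histone demethylases went the other way, with KDM1A up and KDM3A, KDM5B and JMJD1C down among 18 (1 and 4 adjusted over the list alone). Their set test was past the threshold (adjusted p = 0.0165), but adjusted p = 0.310 with an estimated correlation. PBRM1 and HELLS rose and CHD9 fell by 0.16 among 30 remodellers (4 and 2 adjusted over the list alone), HAT1 rose among 11 acetyltransferases (1 and 0), and ASXL2 rose among 15 genes of Polycomb repressive complex 1 and related (0 and 0). No deacetylase of 16 changed, by either adjustment. Set tests for these classes had adjusted p from 0.577 to 0.896, the mutated genes, with EZH2, EED, SUZ12 and CTCF up among 17 (4 and 0 adjusted over the list alone), 0.0728 (0.0462 with quantile normalization), and all epigenetic genes together 0.545. The Polycomb repressive complex 1 and related list had a median slope of 0.02 and the deacetylases 0.01, both positive, while their set tests pointed down.

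**Figure D3:**
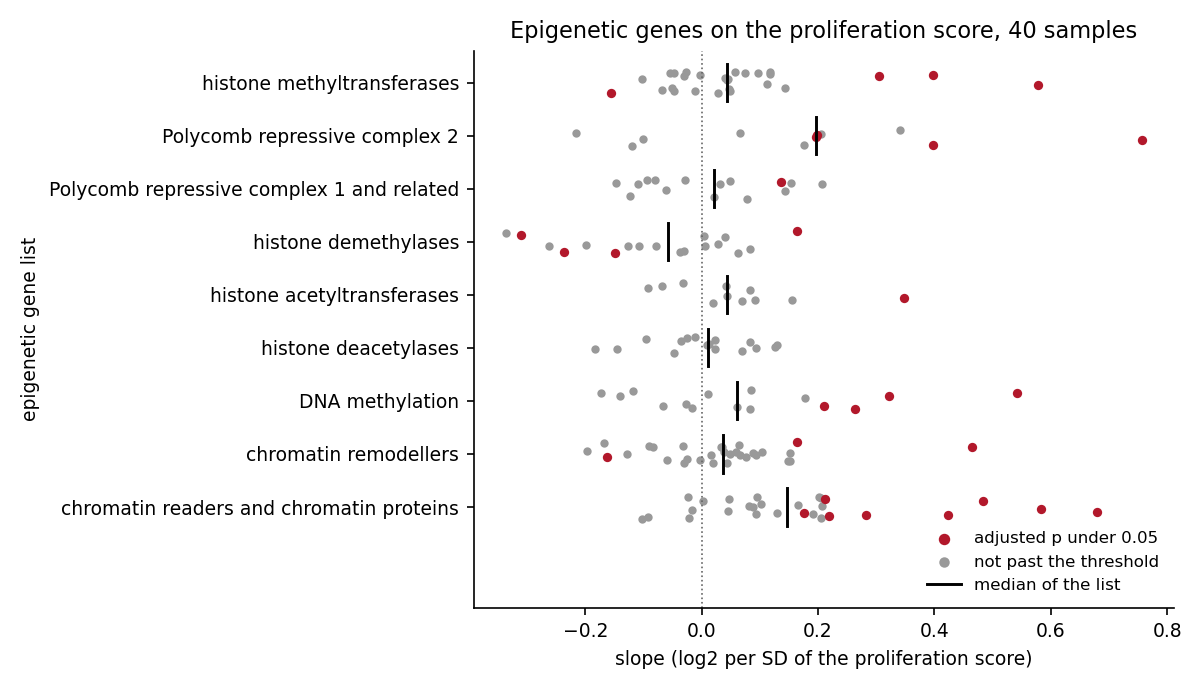
Slope of each tested epigenetic gene on the proliferation score in 40 samples (log2 per SD of the score, x axis), by class. Red points have an adjusted p under 0.05 over all genes, 24 of them to the right of 0 and 5 to the left, and black bars are class medians.

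Outside chromatin, the steepest rises with proliferation were in E2F7 (slope 0.96 ± 0.09), a repressor of E2F targets, BIRC5 (0.92 ± 0.06), the survivin gene, PBK (0.92 ± 0.10), a mitotic kinase, TK1 (0.91 ± 0.11), a thymidine kinase, and SPC25 (0.90 ± 0.08), a kinetochore gene. The steepest falls were in TARP (-1.30 ± 0.29), a transcript of the T-cell receptor gamma locus, CCR9 (-1.14 ± 0.24), a thymus-homing receptor, and SCGB3A1 (-1.09 ± 0.32). VPREB1 (-1.07 ± 0.28), a surrogate light chain gene, and SOCS2 (-1.05 ± 0.36), a cytokine signalling inhibitor, completed the 5 steepest. Few members of the other lists changed. CD7 fell by 0.43 in the pan T cell list, VPREB1 in the B cell list, PTPN2 rose by 0.20 among tumour suppressors and IFI27 by 0.61 in the interferon list, named after their values were seen. No single gene passed among oncogenes or targets of TAL1 and NOTCH1, nor among immature, cortical, mature T cell, monocyte, granulocyte precursor, erythroid, NK, platelet and immediate early genes. Adjusted over the list alone, 1 oncogene rose and 1 fell and 1 platelet gene rose. Median slopes still lay outside those of random lists for cortical (0.36), immature (-0.26), oncogene (-0.25), TAL1 target (-0.15), erythroid (-0.13), NK (-0.07), monocyte (0.14), platelet (0.26), tumour suppressor (0.12) and interferon genes (0.21), and among epigenetic lists for PRC2 (0.20), readers (0.15), mutated genes (0.12) and demethylases (-0.06), with unadjusted p from 0.0002, the smallest these lists can give, to 0.0420. This ranking was chosen after the data were seen and takes no account of correlation between the members of a list. In 100 permutations of the score at most 2 genes were called. The falls of CHD9, KDM3A, KMT5B, JMJD1C and SOCS2 each lost their call in 1 or more alternatives.

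Leukaemias rich in cortical thymocyte genes, which mark the CD1-positive stage of thymus development, had higher expression of CHRNA3, NOTCH3 and CR2 and lower expression of ST18, MYCN and CD34. CHRNA3, a nicotinic receptor subunit, rose 2.95-fold per SD of the cortical score (slope 1.56 ± 0.14 SE, adjusted p = 1.66e-09, n = 40), and CR2 (1.52 ± 0.32), LINC01120 (1.31 ± 0.25), the neuroligin gene NLGN4X (1.26 ± 0.28) and CR1 (1.24 ± 0.32) followed. ST18 (-1.63 ± 0.25) and ZNF521 (-1.52 ± 0.31), both zinc-finger genes, fell most, with HPGDS (-1.48 ± 0.30), a prostaglandin D synthase, MYCN (-1.36 ± 0.20), a MYC family oncogene, and HPGD (-1.33 ± 0.31), which breaks down prostaglandins. Of 11943 tested genes 221 rose and 195 fell, and permuted scores called at most 1 gene in 100 runs.

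Of 171 epigenetic genes 5 rose and 4 fell (5 and 5 adjusted over the list alone), a share of 5.26%, against 3.48% of all tested genes. Risers were MBD2 (0.27 ± 0.06), a reader of methylated DNA, PCGF5 (0.39 ± 0.09), a Polycomb subunit, the acetyltransferase KAT2B (0.41 ± 0.10), USP7 (0.34 ± 0.09) and the methyltransferase SMYD2 (0.36 ± 0.10). JARID2 (-0.42 ± 0.08), an accessory subunit of PRC2, the demethylases KDM2A (-0.19 ± 0.05) and KDM5B (-0.33 ± 0.08), and TRIM24 (-0.25 ± 0.07) fell. Histone demethylases fell as a class by camera (adjusted p = 0.0252), with 2 of 18 down, but adjusted p = 0.614 with an estimated correlation. The other 8 classes, the mutated genes and all epigenetic genes had adjusted p from 0.644 to 0.976. PRC2 had a positive median slope (0.07) while its test pointed down. NOTCH3 (0.65) and CR2 rose in the NOTCH1 list of 9 (4 and 0 adjusted over the list alone), and CD34, ANPEP and HHEX, stem and progenitor genes, fell among 12 immature genes (0 and 8 adjusted over the list alone). LEF1 rose among tumour suppressors, ARID5B and STAT5A fell among TAL1 targets and ATF3 fell among immediate early genes, while no single gene passed in the remaining lists. By the same ranking, median slopes lay outside random lists for NOTCH1 target (0.44), erythroid (0.37), monocyte (0.26), proliferation (0.18), interferon (0.10), immature (-0.43), oncogene (-0.20), TAL1 target (-0.09), immediate early (-0.08), demethylase (-0.06), DNA methylation (-0.05) and all epigenetic genes (-0.01), with unadjusted p from 0.0002 to 0.0456. These members were named after their values were seen. The cortical score itself lay in 2 separate sets of 14 and 26 samples, which held 82.2% of its variance. With the set as a covariate, chosen after the data were seen, limma called 0 genes, with little of the score's variance left within the sets. Of 11943 tested genes 545 had an unadjusted limma p under 0.05. The slope of CR2 then turned to -0.0736 and that of MYCN shrank to -0.231. The calls of KAT2B, USP7, SMYD2 and KDM2A also ended with the median of probe sets, of USP7 and KDM5B with cell type or proliferation scores as covariates, and of CR1 without the additional arrays.

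Leukaemias with more expression of immature or stem-like genes had less expression of CD1E, CD1B, RAG1 and PTCRA and more of MYCN and LYL1. CD1E fell by 2.57 log2 per SD of the immature score (SE 0.35, adjusted p = 3.50e-05, n = 40), CD1B by 2.12, the recombinase RAG1 by 1.36, CHRNA3 by 1.35 and PTCRA, the pre-T-cell receptor alpha chain, by 1.34. Of the 12 cortical genes 8 fell and none rose (0 and 12 adjusted over the list alone). ST18 (1.54 ± 0.27), ZNF521 (1.30 ± 0.33), HPGDS (1.22 ± 0.33), MYCN (1.14 ± 0.23) and LATS2 (1.12 ± 0.18), a kinase of the Hippo pathway, rose most. LYL1 and MEF2C rose among 7 oncogenes, with slopes of 0.53 and 0.76, NOTCH3 fell by 0.64 among NOTCH1 targets, RRM2 by 0.44 among 23 proliferation genes (0 and 16 adjusted over the list alone), and LEF1 by 0.40 among tumour suppressors. These members were named after their values were seen, and no single gene passed in the lists of TAL1 targets, T cells, other cell types, immediate early and interferon genes. Adjusted over the list alone, 2 immediate early genes rose and 1 pan T cell gene fell. By the same ranking, median slopes lay outside random lists for oncogenes (0.27), immediate early (0.19), NK (0.19), B cell (0.13), TAL1 target (0.11), demethylase (0.05), cortical (-0.91), proliferation (-0.27), NOTCH1 target (-0.26), erythroid (-0.19), pan T cell (-0.14) and reader genes (-0.07), with unadjusted p from 0.0002 to 0.0296. In total 159 genes rose and 222 fell of 11943, and 100 permuted scores called at most 2.

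Epigenetic genes were split, with 4 up and 4 down of 171 (4 and 6 adjusted over the list alone). JARID2 (0.41 ± 0.08), the metabolic enzyme IDH1 (0.27 ± 0.06), KDM5B (0.35 ± 0.08) and JMJD1C (0.19 ± 0.05) rose. HDAC4 (-0.70 ± 0.15), USP7 (-0.38 ± 0.09), MBD2 (-0.26 ± 0.06) and ING5 (-0.28 ± 0.07), a reader of methylated histone H3, fell. No class passed camera (adjusted p from 0.0964 to 0.941), although demethylases did without the 3 arrays of high GAPDH ratio (0.0342, chosen after the data were seen) and the mutated genes with the median of probe sets (0.0430), and the median and the test differed in sign for no class. The total of 381 genes was 243 with 4 cell type scores as covariates, 205 with a median score and 248 with the proliferation score as a covariate, and the calls of IDH1, JMJD1C, KDM5B, HDAC4, USP7, MBD2, ING5, ZNF521 and HPGDS each ended in 1 or more alternatives.

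PRC2 genes and proliferation genes went together across leukaemias, the only 1 of 13 tests in this family past the threshold. The scores of proliferation and PRC2 had r = 0.579 (permutation p = 0.00016, adjusted p = 0.00208, n = 40) and rho = 0.515 (permutation p = 0.00083), with r = 0.525 without the 2 samples farthest in proliferation. The PRC2 score includes the 1 sample that lay far below the rest in EZH2. Proliferation went with DNA methylation genes at r = 0.396 (permutation p = 0.0111, adjusted p = 0.0594; rho = 0.356, permutation p = 0.0243) and against immature genes at r = -0.387 (permutation p = 0.0137, adjusted p = 0.0594; rho = -0.412, permutation p = 0.00853). Without the 2 farthest samples these were 0.371 and -0.359. Cortical with immature genes had r = -0.616 within the 14 samples of the lower cortical set (permutation p = 0.0197, adjusted p = 0.0641; rho = -0.609, permutation p = 0.0241) and -0.316 within the other 26 (permutation p = 0.116, adjusted p = 0.302; rho = -0.175, permutation p = 0.393), or -0.336 and -0.147 without the 2 farthest samples, so neither passed. The remaining tests, among them proliferation with monocyte genes, pan T cell with monocyte genes, the cortical score with other lists within its sets, and the GAPDH ratio within 37 arrays, had adjusted p from 0.375 to 0.577. Within the 15 arrays low in a group of probe sets that follow PRMT1, the PRC2 relation had r = 0.539 and adjusted p = 0.238.

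Single genes of the PRC2 and maintenance methylation machinery also rose and fell together, but given the proliferation score only EZH2 with SUZ12 kept its call among them. Of 30 fixed gene pairs 27 were run, in 34 tests, and 10 passed, all positive; the other 3 pairs were not analysed here. EZH2 went with SUZ12 at r = 0.627 within the 39 samples of its higher set (permutation p = 8e-05, adjusted p = 0.000765; rho = 0.670, permutation p = 1e-05, the smallest that 100000 permutations can give). DNMT1, the maintenance DNA methyltransferase, went with its recruiter UHRF1 at r = 0.615 (permutation p = 2e-05, adjusted p = 0.00034, n = 38; rho = 0.588, permutation p = 0.0001). Without the 2 farthest samples the values were 0.561 and 0.604. NOTCH3, a NOTCH1 target, went with PTCRA at r = 0.833 (permutation p = 1e-05, adjusted p = 0.00034, n = 40; rho = 0.825, permutation p = 1e-05), and 0.810 without the 2 farthest. Within 30 samples NOTCH3 went with DTX1, a regulator of NOTCH, at r = 0.648 (permutation p = 0.00016, adjusted p = 0.000907; rho = 0.621, permutation p = 0.00034; 0.588 without the 2 farthest). The relation of NOTCH3 with HES1 (r = 0.437, permutation p = 0.00496, adjusted p = 0.0187, n = 40; rho = 0.352, permutation p = 0.0265) had r = 0.364 without the 2 farthest samples and was no longer past the threshold (adjusted p = 0.075). Its call also ended with rho (adjusted p = 0.0902) and without the 3 arrays of high GAPDH ratio (r = 0.367). It ended as well within the 25 arrays high (r = 0.408) and the 15 low (0.308) in the probe sets that follow PRMT1. TAL1 and ARID5B, one of its targets, had r = 0.597 within the 17 samples high in TAL1 (permutation p = 0.0143, adjusted p = 0.0487; rho = 0.654, permutation p = 0.00509; 0.651 without the 2 farthest), but the call ended in 5 alternatives over all arrays or most of them. EZH2 also went with EED (r = 0.525), DNMT1 (0.589), UHRF1 (0.630) and the proliferation marker MKI67 (0.569), with adjusted p from 0.000765 to 0.00259. Their Spearman's rho was 0.613, 0.617, 0.510 and 0.524 in that order, with permutation p from 3e-05 to 0.00121, and r without the 2 farthest was 0.476, 0.530, 0.439 and 0.452. Given the proliferation score, 5 pairs passed: EZH2 with SUZ12, TAL1 with ARID5B, and NOTCH3 with DTX1, PTCRA and HES1. The calls ended for EZH2 with EED (r = 0.019), MKI67 (0.048), DNMT1 (0.256) and UHRF1 (0.387), and for DNMT1 with UHRF1 (0.415). Pairs with no relation past the threshold included CREBBP with EP300, KMT2C with KMT2D, DNMT3A with DNMT3B, TET1 with TET2, HDAC1 with HDAC2, SMARCA2 with SMARCA4, CD1A with RAG1, and CDKN2A with CDKN2B. EZH2 with SUZ12 had r = 0.120 and no call when a gene was the median of its probe sets.

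**Figure D4:**
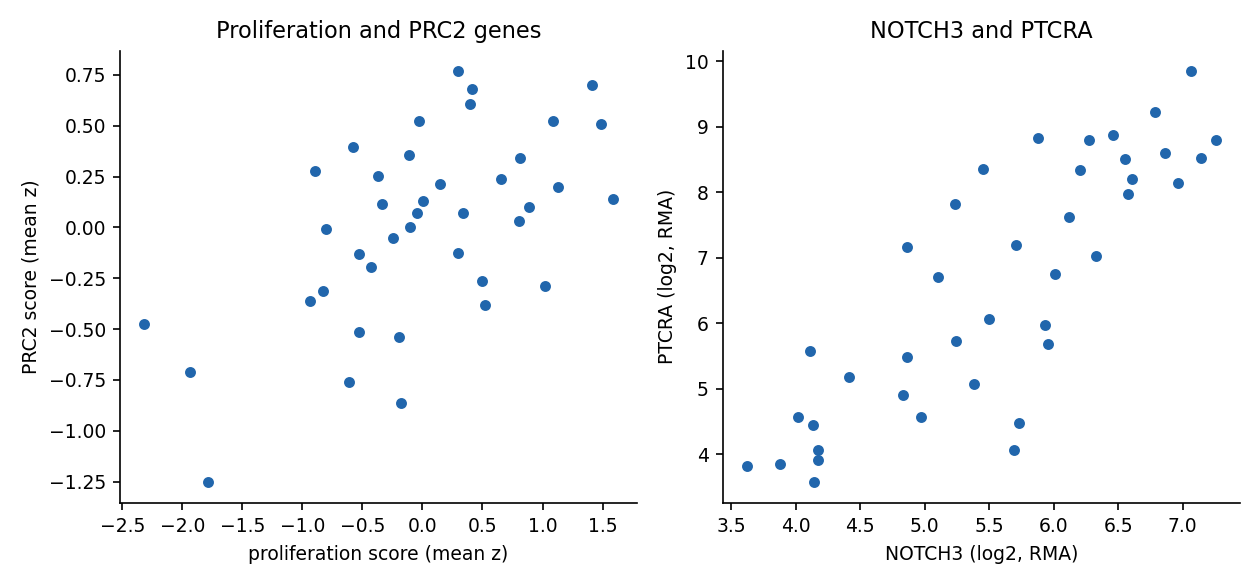
Left, PRC2 score against proliferation score (mean z, both axes) and right, PTCRA against NOTCH3 (log2, both axes), each point 1 of 40 samples. Pearson's r was 0.579 on the left and 0.833 on the right.

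As a batch check, the 3 arrays described as additional differed from the other 37 in 301 genes, 209 higher and 92 lower of 11955. NRARP, a NOTCH target, was at 6.44 ± 2.58 log2 (SD, n = 3) against 3.62 ± 0.46 (n = 37), and ANKRD1, a muscle ankyrin repeat gene, at 7.11 ± 3.82 against 3.20 ± 0.79 (limma adjusted p = 0.000261 and 0.00155). RNASET2, a ribonuclease, was at 7.03 ± 1.42 against 9.21 ± 0.60 (adjusted p = 0.00217). The epigenetic genes SUZ12 and CHD6 were higher and KMT2E, HDAC8, TET2 and EP400 lower among 171. These genes were named after their values were seen, and NRARP was the only further listed gene that differed. Leaving out replicate 20 left 7 genes, replicate 19 left 116 and replicate 29 left 101, so single arrays decide the count. Replicates 19 and 20 also had the highest TLX3 levels of all samples, 4.22 and 3.75 log2, both above background, while replicate 29 had 2.32. A technical difference can therefore not be told apart from a difference between the leukaemias themselves.

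Of the 3 largest axes of variation, 1 went with immature genes and 1 with genes of other blood cells, and the first went with immediate early genes in 1 of its 2 sets of samples. The first principal component of the 2000 most variable genes took 16.2% of variance and lay in 2 sets of 26 and 14 samples. Within the 26, immediate early genes such as FOS and JUN went against it at r = -0.690 (permutation p = 0.00013, adjusted p = 0.0024; rho = -0.666, permutation p = 0.00032; -0.651 without the 2 farthest), but within the 14 at r = 0.274 (permutation p = 0.341, adjusted p = 0.631; rho = -0.011, permutation p = 0.976; -0.296 without). The second component (10.4%) went with the immature score at r = 0.780 (permutation p = 1e-05, adjusted p = 0.000277, n = 40; rho = 0.707, permutation p = 1e-05; 0.724 without the 2 farthest). It went against NOTCH1 targets at r = -0.540 (permutation p = 0.00035, adjusted p = 0.00555; rho = -0.587, permutation p = 8e-05; -0.594 without) and with histone demethylases at r = 0.463 (permutation p = 0.00269, adjusted p = 0.0332; rho = 0.454, permutation p = 0.00341; 0.511 without). The third component (8.04%) went with the monocyte score at r = 0.741 (permutation p = 1e-05, adjusted p = 0.000277; rho = 0.657, permutation p = 1e-05; 0.676 without). B cell (r = 0.654), NK and cytotoxic (0.654), platelet (0.677, n = 36) and granulocyte precursor scores (0.495, n = 35) went the same way, with adjusted p from 0.000277 to 0.0323, rho from 0.411 to 0.601 and r from 0.399 to 0.652 without the 2 farthest. The call of the granulocyte precursor score ended with rho (adjusted p = 0.123) and without the 2 farthest samples (adjusted p = 0.160). In all 111 such tests were run, and no other passed. The first component was tested only within its 2 sets, so its relation to the lists across the sets was not tested.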

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

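The 3 genes of this part stood out only after their levels were seen, and no tests of their own were chosen for them. Keratin genes of the skin had signal in many of these leukaemia samples, although they had been chosen as genes of an unrelated tissue. KRT1, a keratin of upper skin layers, lay over 2 log2 above the background of the other unrelated genes on 20 of 40 arrays, with a highest level of 9.83 log2 and an SD of 2.41. KRT2, another skin keratin, did so on 7 arrays (highest 7.55, SD 1.42) and GNRH1, a hormone gene of the hypothalamus, on 3 (highest 5.79, SD 0.51). They set the background level and were also among the genes of the 3 regressions, where none passed the threshold (lowest adjusted p = 0.0630, for KRT2 with the cortical score). No explanation was tested.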

How the results depend on the processing

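The tests that used the ACTB ratio, the arrays without high GAPDH ratios, random lists, the PRMT1 probe-set signature or the separate sets were chosen after seeing the data. Of the alternatives to the chief results 333 kept their side of the threshold (or a count within 1.5 times). A further 23 counts moved, 8 results passed and 1 ceased to pass. Among single genes, pairs and lists 1667 kept theirs, 18 passed, 97 ceased and 4 reversed. A change of sign counted as reversed only for results past the threshold in the main analysis. Those kept or newly passed can therefore include changes of sign. For the spread of lists, a ratio that crossed 1 counted as kept unless the main result had passed. Genes called with proliferation ranged from 1153 to 1844 over 12 alternatives. With the separate sets of the cortical score as a covariate, limma called 0 genes, against 416 without it. Of 11943 tested genes 545 had an unadjusted limma p under 0.05. None of the 9 epigenetic genes kept its call, and 0 lists passed. The slopes of PCGF5 (-0.00099), TRIM24 (0.0636) and CR2 (-0.0736) reversed. Those of ST18 (-1.64), MBD2 (0.267), SMYD2 (0.339), KDM5B (-0.344) and KAT2B (0.541) held their size. The slopes of KDM2A (-0.02), USP7 (0.113), JARID2 (-0.263), ZNF521 (-0.85), MYCN (-0.231) and CR1 (0.134) shrank. So did those of LINC01120 (0.495), HPGD (-0.741), HPGDS (-1.08), NLGN4X (0.995) and CHRNA3 (1.14). None of these genes had a call, and the covariate takes 82.2% of the score's variance, which lowers the precision. Array weights gave 667 genes and 14 epigenetic genes for this score, and all epigenetic genes had a lower median slope than random lists (p = 0.0150). With an estimated correlation 0 lists passed for proliferation (2 before) and 0 for the cortical score (1 before). The 381 genes of the immature score became 243 with 4 cell type scores, 205 with a median score and 248 with the proliferation score as covariate, and 1 list passed without the 3 arrays of high GAPDH ratio. Score pairs past the threshold, 1 before, were 3 with the median of probe sets, 4 given cell type scores, 3 given the signature and 0 within the 15 arrays low in it. Proliferation passed with immature genes (r = -0.444 with the median of probe sets, -0.398 given the signature) and with DNA methylation (0.480, 0.395 and, given cell type scores, 0.403). Given cell type scores, cortical with immature genes within 26 samples (-0.573) and pan T cell with monocyte genes (0.434, given the other 3) passed. Within the 15 arrays proliferation with PRC2 had r = 0.539 and no call, 1 gene pair passed of 10, and TAL1 with ARID5B reversed to -0.0945; fewer samples lower the power there. Given proliferation 5 gene pairs passed. The 301 genes of the additional arrays became 454 without a filter, 154 with quantile normalization, 464 with the GAPDH ratio as covariate, and 7 to 116 with a replicate left out: 116 without replicate 19, 7 without replicate 20 and 101 without replicate 29, where 2 arrays remain. Elsewhere the cause was not tested. The 3 pairs not analysed here, the unequal-variance fits of BHLHE22 and NKX2-5 and partial correlations in the smallest sets gave no value. Genes near background, such as TLX3, are limited by the signal.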

Other observations

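The tests of the probe-set signature and of PHF6 in this part were chosen after the results were seen, as was the correlation with the ACTB ratio. Classes of epigenetic genes rose and fell together across leukaemias. Among 27 scores, 377 tests were run, and 19 of the pooled pairs passed, all with a positive r. Histone methyltransferases went with DNA methylation genes at r = 0.788 (permutation p = 1e-05, adjusted p = 0.000754, n = 40; rho = 0.591, permutation p = 9e-05; 0.636 without the 2 farthest samples). PRC2 went with the list of chromatin readers and chromatin proteins at r = 0.771 (permutation p = 1e-05, adjusted p = 0.000754). Their rho was 0.717 (permutation p = 1e-05), and r was 0.687 without the 2 farthest samples. The same list, which includes histone variants and chaperones, went with proliferation at r = 0.688 (same p values). Here rho was 0.716 (permutation p = 1e-05), and r was 0.608 without the 2 farthest samples. Here 1e-05 is the smallest p the permutations can give.

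Some lists of blood cell genes also went together. The monocyte score went with the NK and cytotoxic score at r = 0.764 (permutation p = 1e-05, adjusted p = 0.000754, n = 40; rho = 0.759, permutation p = 1e-05; 0.666 without the 2 farthest samples). Mature T cell genes went with pan T cell genes at r = 0.692 (same p values; rho = 0.736, permutation p = 1e-05; 0.688 without). The Polycomb repressive complex 1 and related score went with the GAPDH ratio within 37 arrays at r = 0.467 (permutation p = 0.00382, adjusted p = 0.0497; rho = 0.523, permutation p = 0.00119; 0.476 without). Proliferation had r = -0.248 with the ACTB ratio (permutation p = 0.124, n = 40; rho = -0.359, permutation p = 0.0238; -0.297 without) and r = -0.346 (permutation p = 0.0350) within the 37 arrays without a high GAPDH ratio, in a family of its own that was not adjusted.

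The probe set of PRMT1 was followed by 28 others, which made a signature of 29 probe sets at r over 0.85, 24 genes named, among them GEMIN7, PSMD3, BRD2 and WDR5. It put 15 arrays low and 25 high, as PRMT1 did, with a gap of 6.41 SD, or 6.34 after quantile normalization; the probe sets were chosen to follow PRMT1, so this split is no separate evidence. After both control ratios were regressed out the gap was 6.72 SD, and they took 4.32% of its variance, which argues against RNA quality. What stays open is an effect on single probe sets, since 24 other probe sets of 14 of these genes had a median r of 0.302 with the signature, from -0.256 to 0.872, between the bounds set. Those of BRD2 (r = -0.212 and -0.110) and WDR5 (r = -0.013) did not follow it. Also open is RNA from other cell types, whose scores took 15.4% of the variance and left a gap of 3.92 SD, just under the 4 SD asked for. No biological explanation was tested.

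The 24 epigenetic genes that rose with proliferation were set against 3 explanations, although epigenetic genes as a group did not pass camera (adjusted p = 0.545). With the ACTB ratio as a covariate 24 epigenetic genes rose, with 4 cell type scores 21 and with the signature 27, against 24 without a covariate. These counts argue against RNA quality, the 4 scored cell types (monocyte, erythroid, B and NK cells) or the signature as the whole cause. Scores of mature T cells, granulocyte precursors and platelets were not covariates, so the counts cannot speak to those cells. No biological explanation was tested, since the labels name 1 group.

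PHF6 was low in 6 samples, with a gap of 5.36 SD. After both control ratios were regressed out the gap was 5.16 SD, with 1.77% of variance taken, which argues against RNA quality. A fault of 1 probe set stays open: 4 of the 6 samples were also among the 6 lowest on the second probe set, which had a mean of 4.11 log2, near background, and no split of its own (simulated p = 0.278). The r of 0.709 between the 2 probe sets goes against such a fault, but no bound had been set for it. No biological explanation was tested.

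For the 3 additional arrays, 2 of 100 splits into 3 and 37 arrays gave as many genes, the real one with 301 included, a share under the 5% set beforehand. With so few splits drawn and a count that depends on single arrays, this share cannot exclude chance. The highest other split called 826 genes, several times the real count, and held 1 array of high GAPDH ratio. Putting the 3 arrays of high GAPDH ratio apart called 680. Of these 680, 97 were higher and 583 lower. The median of the other splits drawn was 0 genes. The split of 826 genes was a single draw, and that of 680 was chosen by the GAPDH ratio. They therefore do not settle whether the samples hold a structure, and no source was tested. A single array can decide a count, since 7 genes were left without replicate 20.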
